A study of Drosophila melanogaster with 4 samples.

How the data were processed

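The series holds 4 samples of mixed Drosophila melanogaster embryos of 0 to 24 h: 2 Pol II ChIP samples from separate chromatin extractions and 2 input samples. Per the labels, libraries were made with the standard Illumina protocol with a size selection of 150 to 200 bp and sequenced single-end on a Genome Analyzer II with reads of 36 nt. Region lists of the 2 ChIP samples and a list of the whole series were analysed; the input samples were not used here. Samples were grouped by the label that says whether the DNA is ChIP or input, and replicates were numbered in the order of the samples, which the labelled extraction numbers follow.

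Per the file headers, the deposited lists are GFF3 files on FlyBase r5.1, and their source column names PeakSeq, a program that calls regions of enriched read density. The aligner, the read filters, the control used in calling and the calling threshold are not given in the sources used here. Each region has a start, an end and a score; the score column of the deposited files carries no name or unit, so the authors' score was used to describe, rank and filter regions and was compared between replicates on a log2 scale. All scores were above 0. Regions were called separately in each replicate, since each replicate has its own list and region names. Neighbouring regions of a replicate list were at least 200 bp apart. Such lists hold only what passed the caller's threshold, so a position missing from a list is not shown to lack Pol II, and a difference in depth between extractions changes how many regions pass.

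Scores on a given chromosome were often whole multiples of a step, or such a multiple divided by a whole number up to 4, and the step differed between chromosomes. Steps were estimated in alternate regions of each list and tested in the remaining ones with a relative tolerance of 1e-05, on chromosomes with at least 20 regions and, on those with many regions, in the narrowest 30%. Scores from different chromosomes may therefore not share a scale, which limits rankings and filters by score over the whole genome. No read counts were derived from the steps.

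Overlap was taken as at least 1 bp. For the replicate lists its null came from 100000 circular shifts of a list within each chromosome, with the furthest region end over the 3 lists as the chromosome length. Replicate scores of a whole-series region were the mean scores of the replicate regions it overlaps. Spearman intervals came from 2000 bootstrap samples of regions. Shares have Wilson 95% intervals, except the share on X, whose interval is exact, and counts per Mb have exact Poisson intervals; all cover counting error only. Differences in median width and in regions per 1 Mb window were tested with 100000 permutations, with a threshold of 0.05. Runs of regions less than 1000 bp apart were compared with 1000 random placements of the regions of each chromosome, with widths kept and no overlaps. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9. The overlap, chain and step routines were tested on simulated data. In lists of the size of replicate 1, 197 of 200 planted shared regions were recovered, and 5% of 40 unrelated simulated pairs had p under 0.05. All 50 planted runs of regions were found, and a planted step was recovered in 10 of 10 simulations. Planted shared regions were exact copies, planted runs had gaps well under the limit, and planted steps were larger than nearly all estimated ones. These simulations therefore check the routines and do not measure their power on the deposited lists.

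Before the data were examined, the comparisons, their tests, the alternatives listed as planned and the rule for naming regions were fixed. The rule takes the 20 highest-scoring whole-series regions that overlap both replicates, the 10 widest whole-series regions and the 5 highest-scoring regions of each replicate that overlap none of the other, with ties given to the wider region. The alternatives were a stricter overlap, the upper 50% of a list by score, equal numbers of top regions, width in place of score, and either replicate list alone. The comparison of matched with unmatched regions, the width and score deciles, runs of regions, broad regions, the fullest windows, arm ends, regions outside U and the comparison of U with other chromosomes were chosen after the data were seen.

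The gene table used here is of genome Release 6, not r5.1, and coordinates were not converted. The planned comparisons with transcription start sites, promoters, gene bodies and gene lists were therefore not analysed here, and regions are given by position.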

Results

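RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected together from 0 to 24 h of development. The mouse monoclonal antibody CTD4H8, raised against a peptide of the repeated carboxyl-terminal domain of the largest Pol II subunit, was used on 2 chromatin extractions, called replicate 1 and replicate 2. The 2 input samples of the series, sequenced without immunoprecipitation, were not analysed here, so no background level stands beside the values. Each replicate had its own list of enriched regions, and a further list covered the whole series. Replicate 1 held 5763 regions covering 1267 kb, replicate 2 held 8872 regions covering 2573 kb, and the whole-series list held 4366 regions covering 1874 kb. The lists give no read counts, so the sequencing depth of each replicate is unknown. Positions are on FlyBase release r5.1 and count from 1, and no gene was assigned to a region because the gene table used here is of another genome release. With a single list per extraction, the tests below compare these lists, and the p-values carry no estimate of the spread between further extractions.

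The first question was how far both extractions placed Pol II at the same positions. Of the 5763 replicate 1 regions, 4608 overlapped a replicate 2 region by at least 1 bp (Wilson 95% interval of the share 78.9% to 81.0%). Of the 8872 replicate 2 regions, 4426 (49.9%, interval 48.8% to 50.9%) overlapped a replicate 1 region, which left 4446 without a counterpart. Circular shifts of one list within each chromosome gave 203 overlapping replicate 1 regions on average, so the observed number was 22.7 times the shifted mean (one-sided permutation test, p = 1e-05, the smallest that 100000 shifts can give). For replicate 2 the observed number was 22.0 times the shifted mean (one-sided permutation test, p = 1e-05). When an overlap had to cover at least 50% of both regions, the shares fell to 48.9% of replicate 1 and 31.8% of replicate 2. With the 5763 highest-scoring regions of each list, the shares were 62.8% of replicate 1 and 60.2% of replicate 2, which lists of equal size bring close to each other by construction.

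Regions found in a single replicate were narrower and had a lower median score than shared regions. In replicate 1 the median width was 54 bp for the 1155 unmatched regions and 174 bp for the matched ones, and in replicate 2 the quartiles were 59 and 230 bp for unmatched and 195 and 497 bp for matched regions. The median score was 2.23 for unmatched and 2.59 for matched regions of replicate 1, and 2.15 and 3.13 in replicate 2. In the lowest width decile of replicate 2, 7.32% (Wilson 95% interval 5.78% to 9.22%) of the regions overlapped replicate 1, against 86.1% (83.7% to 88.3%) in the highest. The rise was not steady: the share was 75% in the sixth width decile of replicate 2 and 61.7% in the eighth, with intervals that did not overlap. In replicate 1 the share was 33.6% in the lowest width decile and 97.2% in the highest. A wider region meets an overlap of at least 1 bp more easily, so some rise with width follows from the rule. Its size was not measured, since no shifted share was computed per decile. By score, the share in replicate 1 was higher in the lowest decile (80.2%) than in the following 5 (71.0% to 74.3%), and it reached 94.3% in the highest.

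**Figure D1:**
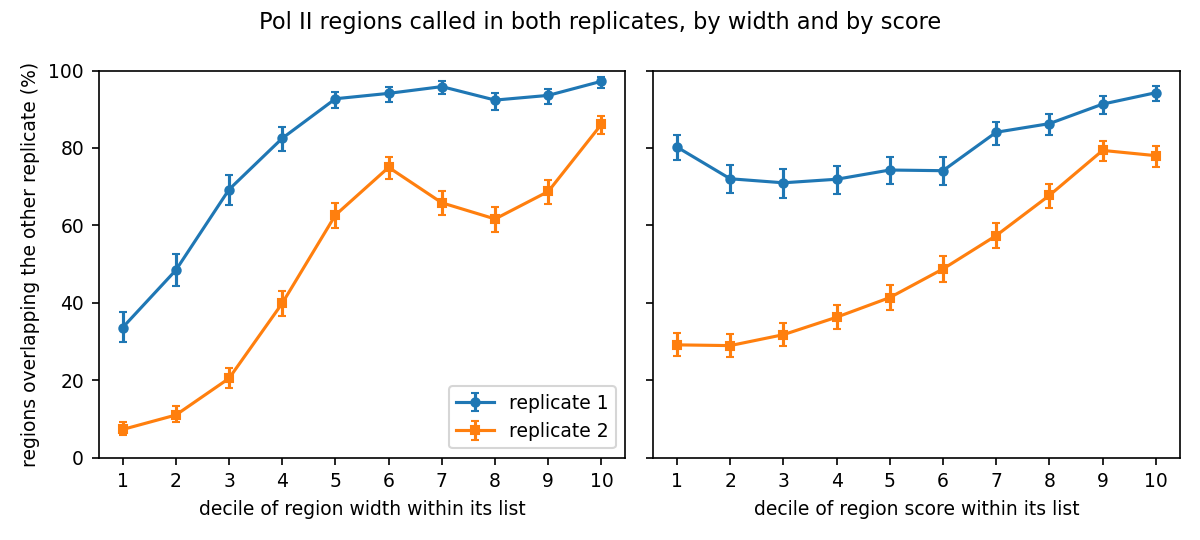
Share of regions of each replicate (y axis, percent) that overlap the other replicate by at least 1 bp, by decile of region width (left) and of score (right) within each list; points are shares and bars are Wilson 95% intervals. In replicate 2 the share is 7.32% in the first and 86.1% in the last width decile, and 29.2% in the first and 78.0% in the last score decile. In replicate 1 the first score decile (80.2%) lies above the next 5. Score deciles pool all chromosomes, U included, where the 170 replicate 2 regions have a median score of 19.3 and 34.7% of them overlap replicate 1.

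The score of a shared region was related between extractions, with wide scatter. Over the 4366 whole-series regions, the Spearman correlation of the replicate scores was 0.55 (bootstrap 95% interval 0.53 to 0.57) and the Pearson correlation of log2 scores was 0.52. These are correlations across regions, which are not independent replicates. By arm, rho was highest on 2L (0.62, 800 regions) and lowest on the small chromosome 4 (0.36, 51 regions) among the chromosome arms. Among regions in the upper 50% of both lists by score, rho was 0.40 over 1995 regions. That cut narrows the range of both scores, which by itself can lower rho. Region width, in place of score, gave rho = 0.60.

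Scores on U, the unplaced scaffolds of the assembly, stood apart. The 58 shared U regions had a median score of 3.21 in replicate 1 and 19.6 in replicate 2, and all 58 scored higher in replicate 2. The median log2 ratio of replicate 2 over replicate 1 was 2.71 on U (SD 0.64 over regions), against 0.19 (SD 0.60) over the 4196 shared regions of the 5 large arms and 0.18 (SD 0.63) over the 61 shared regions of the heterochromatic scaffolds. Replicate 2 held 170 regions on U and replicate 1 held 81, which is 2.10 times as many in replicate 2, against 1.53 times over the 6 chromosome arms. Chromosome 4 held 76 regions in replicate 1 and 150 in replicate 2, so a rise in number was not particular to U. Leaving U out moved rho from 0.55 to 0.56, an alternative chosen after the data were seen.

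**Figure D2:**
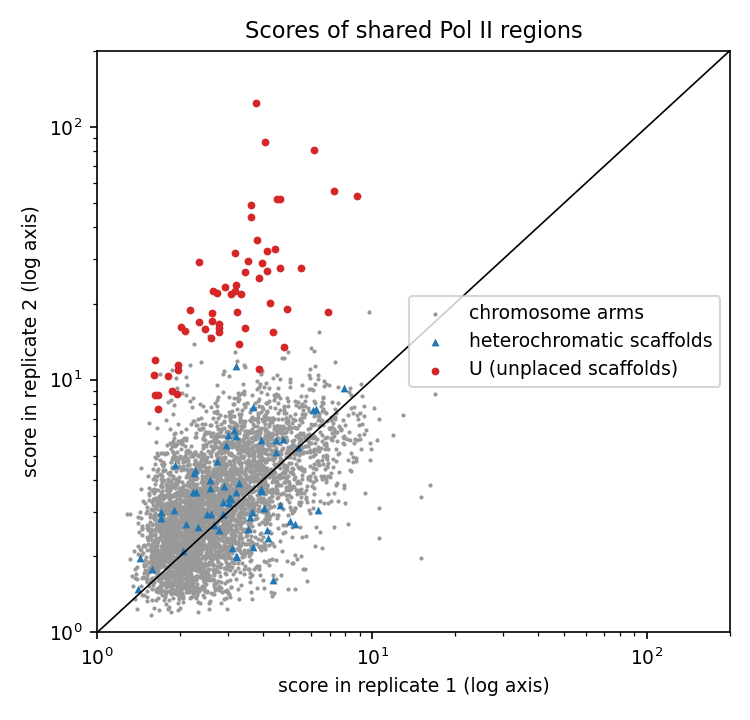
Score of each of the 4366 whole-series regions in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with the line of equal scores. The 58 regions on U (red) all lie above the line, with a median of 19.6 in replicate 2 against 3.21 in replicate 1, while the 61 regions on heterochromatic scaffolds (blue triangles) lie among those of the arms (grey).

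The whole-series list held the positions found in both extractions. All 4366 of its regions overlapped both replicate lists, and the ends of all 4366 were the outer ends of the replicate regions they overlapped. A total of 4103 regions (94.0%) joined a single region of each replicate, and the remaining 263 joined several regions of at least one replicate. For 98.8% of the regions the deposited score equalled the mean of the replicates' mean scores within 0.0001. Its overlap with the replicate lists therefore follows from how it is made up, and no test of that overlap is given. At least 50% of both regions was shared with a replicate 1 region for 69.0% of the list and with a replicate 2 region for 96.5%.

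The number of Pol II regions per Mb differed between chromosome arms. Arm 2R carried 881 whole-series regions, or 41.7 per Mb (exact Poisson 95% interval 39.0 to 44.6), and 3L carried 924, or 38.5 per Mb (36.0 to 41.0). Arm 2L carried 800 (34.8 per Mb, 32.5 to 37.3), 3R 894 (32.0 per Mb, 30.0 to 34.2) and X 697 (31.1 per Mb, 28.8 to 33.5). Chromosome 4 carried 51 regions (41.4 per Mb, 30.8 to 54.5). In the replicate lists it was the densest of the 6 arms, with 76 regions (61.7 per Mb, 48.6 to 77.3) in replicate 1 and 150 (122 per Mb, 103 to 143) in replicate 2, of which 52 overlapped replicate 1. Regions were sparser on the long heterochromatic scaffolds, with 5.87 per Mb on 2RHet, 5.50 on 3LHet and 7.25 on 3RHet, and on U with 5.78 per Mb. XHet was the exception, with 9 regions within 0.0861 Mb. YHet held 1 region in each replicate, at different positions, and none in the whole-series list. Lengths were taken as the furthest region end on each chromosome, a lower bound, and the intervals cover counting error only. On which share of each scaffold reads of 36 nt can be placed was not examined, so fewer called regions do not show less Pol II.

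X held 16.4% of the 4247 regions on the 6 arms (exact 95% interval 15.3% to 17.6%), below its 18.7% of their length (exact binomial test, two-sided, p = 9.05e-05). That test counts each region as independent. Only X was tested, and a low density was not particular to it. Arm 3R had 32.0 regions per Mb (30.0 to 34.2), close to the 31.1 (28.8 to 33.5) of X. Over windows of 1 Mb, X had 31.5 ± 8.53 regions (SD over 22 windows) and the 4 large autosomal arms 36.7 ± 11.5 (94 windows), a difference of -5.11 that did not pass the threshold (two-sided permutation test, p = 0.0517, chosen after the data were seen). In the upper 50% of the list by score, X held 18.2% of the regions (exact binomial test, two-sided, p = 0.518). That cut moved other arms too, with 3R going from 21.1% to 17.4% and 2L from 18.8% to 20.2%. Scores of different chromosomes may not share a scale, so the cut does not show that the low share of X is absent among the strongest regions.

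Along the arms, called Pol II regions thinned out towards most centromeres. The share of sequence there on which reads of 36 nt can be placed was not examined, so a low count does not show less Pol II. The 117 full windows of 1 Mb held a median of 36 regions, with a range of 2 to 69. The Mb nearest the centromere held 2 regions on 2R and 2 on 3L (exact Poisson 95% interval 0.242 to 7.22 for each), 12 on 2L and 11 on X. On 3R it held 38 (26.9 to 52.2), near the median. In the whole-series list the fullest window was the first Mb of 3L, at the telomere end, with 69 regions, and it held 86 in replicate 1 and 112 in replicate 2. In replicate 2 the first Mb of chromosome 4 held more, 130 regions, against 45 in the whole-series list. The counts per window in both replicates rose and fell together, with Spearman rho = 0.87 and Pearson r = 0.89 across windows, which are not independent replicates.

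**Figure D3:**
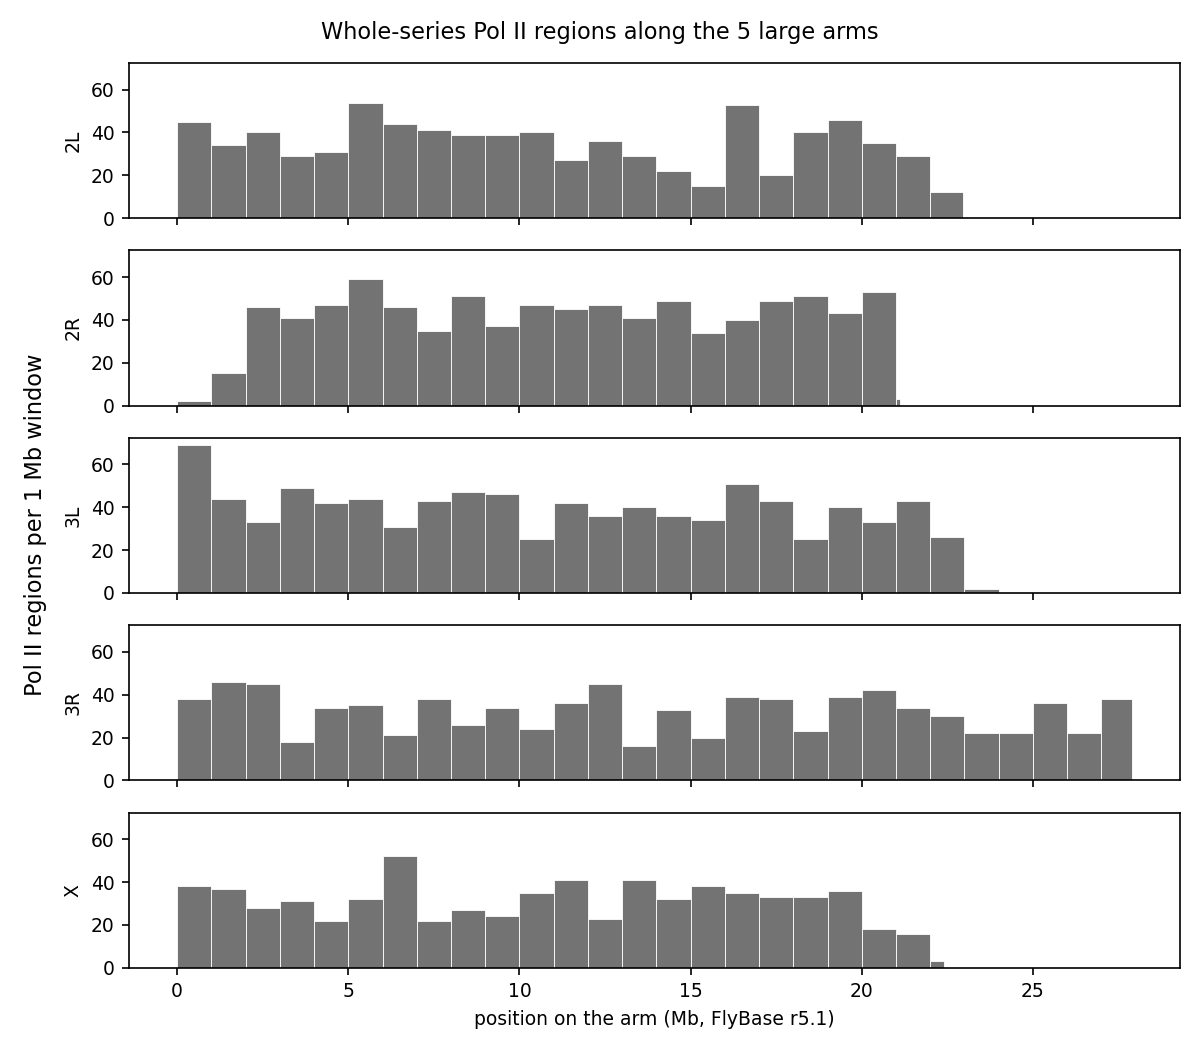
Number of whole-series Pol II regions in each 1 Mb window (y axis) along the 5 large chromosome arms (x axis, position in Mb on FlyBase r5.1), with bars that start at 0. Counts are lowest at the left end of 2R and the right end of 3L, with 2 regions in each outermost full window, and highest in the first window of 3L, with 69; the last bar of an arm can be narrower than 1 Mb.

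The called regions were mostly narrow. A width is a stretch above the caller's unknown threshold, in libraries selected for 150 to 200 bp, so it does not measure the extent of Pol II. The median width was 152 bp in replicate 1 (quartiles 83 and 239 bp), 203 bp in replicate 2 (107 and 363 bp) and 290 bp in the whole-series list (203 and 533 bp). The median in replicate 2 was 51 bp higher than in replicate 1 (two-sided permutation test over regions, p = 1e-05, the smallest that 100000 resamples can give). In the upper 50% of each list by score the difference was 32 bp. A total of 259 replicate 1 regions and 316 replicate 2 regions were narrower than 10 bp, and the narrowest whole-series region was 22 bp.

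The 10 widest whole-series regions lay on 2R, 3R, 2L and 3L and were at least 2568 bp wide. The widest spanned 5172 bp on 2R (15998673 to 16003844) and was a single region in replicate 1, with a score of 3.15, and 2 regions in replicate 2, with a mean score of 2.96. It was followed by 4019 bp on 2L (870414 to 874432), 3308 bp on 2R (7779496 to 7782803), 3256 bp on 3R (7047417 to 7050672) and 3067 bp on 3R (909993 to 913059). The other five were on 3R (5453900 to 5456745 and 2912124 to 2914930), on 3L (19683576 to 19686268) and on 2R (18686532 to 18689208 and 7509228 to 7511795). The 2R region at 7779496 was a single region in both replicates, with a mean score of 4.03 ± 0.55 (SD, n = 2), and the 3L region scored 3.48 in replicate 1 and 5.60 in replicate 2. In all, 310 whole-series regions (7.10%, Wilson 95% interval 6.38% to 7.90%) were at least 1000 bp wide, and they made up 24.1% of the covered length. In the replicate lists the share was 2.15% (124 regions) in replicate 1 and 3.31% (294 regions) in replicate 2. The whole-series list takes outer ends and leaves out unmatched, narrower regions, which raises its broad share and its median width. The 310 broad regions had a median score of 2.92 (quartiles 2.24 and 3.91). That was close to the 2.93 (2.23 and 4.14) of the narrower whole-series regions.

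All 20 of the highest-scoring whole-series regions were on U, a place that rests on replicate 2. Ranked by the replicate 2 score alone, all 20 were also on U, and ranked by the replicate 1 score alone, 0 of 20 were. In replicate 1 the 20 named regions scored 2.34 to 8.78, against up to 17.0 for whole-series regions outside U. The highest, at 8901520 to 8901674, scored 3.77 in replicate 1 and 124 in replicate 2, with a mean of 63.9 ± 85.0 (SD, n = 2). The next were at 8908318 to 8908551, with a mean of 45.7 ± 58.8, and at 7543953 to 7544146, with 43.4 ± 52.8 (SD, n = 2 for each). The spread between replicates was above the mean for each of these 3 regions.

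Outside U, a list chosen after the values were seen, the 20 highest-scoring regions were spread over the 5 large arms, with 5 on X, 5 on 3L, 4 on 3R, 3 on 2L and 3 on 2R. The highest was on X at 10108951 to 10110207, 1257 bp wide, with a mean score of 14.1 ± 6.24 (SD, n = 2). The next included 3L at 9498247 to 9498492 (12.9 ± 5.79), X at 1930355 to 1930596 (10.9 ± 6.43), and 2L at 20223064 to 20223244 (10.0 ± 8.75; SD, n = 2 for each). X at 5794814 to 5795054 scored 12.9 in replicate 1 and 7.27 in replicate 2, with a mean of 10.1. The replicates differed least on 3R at 2060347 to 2060970 (9.38 ± 0.36, SD, n = 2), on 2R at 14560874 to 14561127 (8.89 ± 0.42) and on 3R at 2074636 to 2076242 (8.58 ± 0.52). Another of the 20, on 3R at 2061225 to 2063680, was 2456 bp wide and scored 8.60 ± 1.06 (SD, n = 2).

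The highest-scoring regions found in a single replicate were narrow. In replicate 1 they were on U at 4436395 to 4436422 (score 27.7), on YHet at 205276 to 205329 (24.3), on 3RHet at 2017990 to 2017994 (19.1), on 2L at 14187097 to 14187121 (12.3) and on X at 15398318 to 15398324 (11.6), with widths of 5 to 54 bp. In replicate 2 all 5 were on U, the highest at 9654136 to 9654210 with a score of 103, and then at 7291620 to 7291643 (82.6), 1364682 to 1364690 (77.5), 7211927 to 7212000 (67.1) and 6292561 to 6292584 (67.1), with widths of 9 to 75 bp.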

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

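Alternatives without U, over windows, with runs counted once, and those for runs and broad regions were chosen after the data were seen. Both overlap shares between replicates and the difference in width kept their direction and stayed past the threshold under every alternative run. The share of regions on X below its length kept its direction but did not pass the threshold in the upper 50% by score (18.2%, p = 0.518) or over 1 Mb windows (-5.11 regions, permutation p = 0.0517); scores of different chromosomes may not share a scale, which bears on the first, and the cause was not tested. With either replicate list alone the share on X was 16.3% to 17.6%. Score agreement was 0.57 with at least 50% of both regions shared, 0.40 in the upper 50% and 0.60 for width. The upper 50% narrows the range of both scores, so its lower rho does not show weaker agreement of the strongest regions. The cause of the other differences was not tested. Runs of 3 or more regions numbered 67 with a gap under 500 bp, 184 under 2 kb and 20 in the upper 50%, which holds fewer regions, and 278 to 526 in the replicate lists, which hold more. Broad regions were 0.756% at 2 kb, a stricter limit, and 2.15% to 3.31% in the replicate lists. The whole-series list takes the outer ends of the regions it joins and leaves out unmatched, narrower ones. Both raise its broad share by construction. The share on chromosome 4 was 1.20% in the whole-series list, 0.913% in its upper 50% by score, 1.36% in replicate 1 and 1.76% in replicate 2. Leaving aside the overlap of the whole-series list with the lists it is made of, and its regions in both replicates, which are all of them, 33 of 50 alternatives left the result in place, 15 moved a value, 2 ended a call and none turned a result round. The tally mixes unlike criteria. Overlap shares that fell to 48.9% of replicate 1 and 31.8% of replicate 2 count as in place, while a rho of 0.57 against 0.55 counts as moved. Alternatives for start sites, promoters, gene lists and gene bodies were not run. Depth is unknown and limits how far the difference in list length can be read.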

Other observations

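Except for the test of width-matched regions and the test of regions near replicate 1 regions, the tests below were chosen after the result was seen.

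Pol II regions gathered in runs more often than even placement along a chromosome gives. Full windows of 1 Mb held 2 to 69 regions, so uneven density alone gives some excess, and its part was not measured. Whether a run is a single wider region cut into pieces was not tested. A total of 446 whole-series regions lay in runs of 3 or more regions less than 1 kb apart, and such runs were 23.2 times as frequent as the 5.31 found on average when regions were placed at random on each chromosome (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The excess depended on the distance and the list: it was 49.0 times with gaps under 500 bp, 9.36 times under 2 kb, 12.9 times in replicate 2 alone, 24.0 times in replicate 1 alone and 30.9 times in the upper 50% by score. The longest run by number lay on 3L from 632205 to 643665, with 11 regions covering 61.0% of 11461 bp and 13 regions in each replicate. The next were on 2R from 12716319 to 12727561, with 9 regions covering 67.5% of its length, and on 2L from 16781724 to 16789073, with 7 regions. The 2L run and the 3L run lay in the windows of 50 kb with the most regions, 16750001 to 16800000 on 2L with 19 and 600001 to 650000 on 3L with 18, followed by 6400001 to 6450000 on 2R with 17. Per Mb, runs were most frequent on 3L (30 runs, 1.25 per Mb) and 2R (26 runs, 1.23 per Mb) and least on X (16 runs, 0.714 per Mb) among the 5 large arms; these differences were not tested. Across regions, the Spearman correlation of width and score was 0.21 in replicate 1, 0.05 in replicate 2 and -0.04 in the whole-series list outside U.

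Among shared regions, the values argue against width as the source of the high scores on U in replicate 2. They also argue against a rise common to repeat-rich scaffolds, while repeats particular to U were not tested. Heterochromatic scaffolds, which are also rich in repeats, moved by -0.0113 (log2) relative to the large arms, and arm regions of the same width as the U regions had a median log2 ratio of 0.14, against 2.71 on U. A scale factor set per chromosome by the scoring stays open. The SD of the log2 ratios on U was 1.08 times the median SD of the large arms, as a common factor requires, but the steps do not decide it. The estimated step of the U scores rose 2.49 times between replicates and the scores rose 6.53 times, and on the arms the ratios differed too, with 0.830 for the step and 1.18 for the scores on 2L and 1.59 and 1.14 on 3L. A step is known only up to a ratio of small whole numbers. More Pol II on U in the second extraction cannot be told apart from such a factor, since all 58 regions were higher in replicate 2 and neither read counts nor input were analysed here.

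A scale factor set per chromosome may underlie the steps themselves: held-out scores were multiples of the step of their own chromosome 108 times as often as of the steps of other chromosomes (27.8% against 0.257% of 2460 scores). Their own step was ahead of every other in 19 of the 20 combinations of chromosome and replicate. The exception was 3LHet in replicate 2, where another step matched as many of the 24 scores (20.8% for each), and on X in replicate 2 another step matched 18.4% against 29.8% for its own.

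Whether the 4446 replicate 2 regions without a counterpart lay close to the calling threshold stays open. On the large arms, an unmatched region outscored a matched one with a median probability of 0.264. That restates their lower scores and does not measure the distance to a threshold. In the highest score decile 78.0% of the regions were matched. This decile pools all chromosomes and starts at a score of 5.55, below the median of 19.3 of the 170 replicate 2 regions on U. Of those U regions 34.7% were matched, so U can lower the pooled share, and the share without U was not computed. Whether some of them are pieces or edges of replicate 1 regions cannot be told from their distance. A share of 28.5% lay within 1 kb of a replicate 1 region, against 8.87% on average after shifts. Shifts break the alignment of dense stretches between the lists, so separate neighbouring regions would also raise this share. That leaves the contribution of such pieces open, and no biological explanation was tested.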
